A study of Drosophila melanogaster with 24 samples.

How the data were processed

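The data are RNA sequencing counts from 24 libraries of Drosophila melanogaster males at 10 days of age, 18 from thoraces and 6 from heads, in 8 groups of 3 libraries that the labels call biological replicates. Libraries were made with the TruSeq stranded mRNA kit and sequenced on an Illumina HiSeq instrument. The authors aligned the reads with STAR to genome build BDGP5 and deposited raw read counts per gene, with no normalization. The version of STAR, the annotation and the strand setting of the counts are not given in the sources used here, and the counting tool is not named, although the 5 closing summary rows of each file have the form written by htseq-count. Each file lists 15682 gene symbols. Genes are named by these symbols, and no positions are printed, since the reference annotation used for neighbouring and overlapping genes is of another build.

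Depth was 28.9 to 79.2 M reads in genes per thorax library and 47.5 to 75.7 M per head library, with 12404 to 13424 genes detected per library. The summary rows held 19.4 to 31.2% of reads in thoraces and 22.7 to 25.4% in heads. Counts of reads carry no molecular identifiers, so their counting error understates the technical error.

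Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr (minimum count 10, minimum total 15), libraries were scaled by the trimmed mean of M values (TMM), and a quasi-likelihood model was fitted with 1 mean per group. Two-sided quasi-likelihood F tests were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene is called at an adjusted p under 0.05. The standard error of a log2 fold change is the fold change divided by the square root of F. The procedure was also tested on simulated data, in which it recovered 93% of 2-fold and 96% of 4-fold changes in the 15-library fit, 88% and 96% in the CG6272 fit and 98% and 100% in the head fit. Of the genes called in those simulations 3 of 192, 11 of 195 and 13 of 211 were unchanged ones. Of 100 unchanged lists in each fit 0, 1 and 0 passed the list test at an unadjusted p under 0.05. In these simulations genes were drawn independently, and the control lines did not differ. They therefore do not show how the tests behave where genes are correlated or control lines differ.

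The comparisons numbered 8. The 15 thorax libraries of GFP, white, ProsB1, ProsB5 and Ter94 RNAi shared 1 fit, in which each knockdown was set against the mean of the GFP and white RNAi groups, white against GFP RNAi, ProsB5 against ProsB1 RNAi, and Ter94 RNAi against the mean of the proteasome knockdowns. CG6272 RNAi was fitted with the 6 control libraries alone, because its titles have another form than those of the other thorax groups, so that a library batch cannot be told apart from the knockdown. Heads were fitted apart. The labels give replicate numbers but state no pairing. Replicate numbers were taken to pair the compared libraries where each correlation of within-group residuals lay over 0.1, and other matchings were not tried. This held in ProsB5 against ProsB1 RNAi (0.147 to 0.463) and in heads (0.155 to 0.239). The text gives values with replicate number in the model for these where a call changed. With GFP RNAi all 3 pairs also passed this limit for ProsB5 (0.532 to 0.764) and ProsB1 RNAi (0.128 to 0.434), but not all pairs with white RNAi did (from -0.455 and 0.0555).

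Before the data were examined, 16 pathway lists and 9 marker lists were fixed, together holding 435 genes, of which 434 were matched to symbols in the files. Each list with at least 3 measured members was tested against all other genes with camera (limma 3.58.1, two-sided, preset correlation 0.01), adjusted over the pathway lists or the marker lists of a comparison, without the gene under manipulation. An estimated correlation was the alternative. A member is also given as called adjusted over the list alone, in which the adjustment covers only the list. Genes named were fixed by rule: the gene under manipulation, the 5 largest rises and 5 largest falls among called genes with at least 5 CPM in a compared group and no overlap between libraries, up to 3 members of each pathway list and 2 of each marker list by adjusted p, and Amyrel and CG6272 everywhere. Of 277 named genes with a place in the annotation 125 overlap another gene, among them Amyrel and w, and reads of near-identical copies, such as the Hsp70, lysozyme and maltase genes, are hard to assign. Hsp22 is listed at 0 throughout.

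Overlaps between comparisons were counted as genes called in both with the same sign, against independent lists, and with a different control for each comparison. Other splits of the same libraries into 2 groups were refitted, with reference groups pooled, and their calls counted. Alternatives fixed before the data were examined were DESeq2 1.42.0, relative log expression scaling, no low-count filter, an absolute log2 fold change of at least 1, replicate number in the model, GFP or white RNAi alone as the control, a fit of the compared groups only, a fit of all thorax libraries for CG6272 RNAi, an estimated list correlation and each library left out. Alternatives chosen after the data were seen were calls against each reference group separately, the data without 3 control libraries with ninaE above 100 CPM, the data without 4 libraries with Acp36DE above 5 CPM, and Ter94 RNAi replicates 2 and 3 summed as 1 library. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Ter94 RNAi replicates 2 and 3 lay closer to each other (1.76, chi-square per gene) than any other pair of replicates (11.9 or more), so they may not be independent. No library was left out of the fits reported, and the summary rows were not tested.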

Results

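RNA was sequenced from 18 libraries of thoraces, which are mostly skeletal muscle, and 6 libraries of heads, all from male flies at 10 days of age. Each thorax group held 3 libraries and expressed 1 RNAi transgene in muscle under the Mhc driver. The transgenes were directed at GFP or white, the controls, at Prosbeta1 or Prosbeta5 (ProsB1 and ProsB5 in the labels), at TER94 (Ter94 in the labels) or at CG6272. Prosbeta1 and Prosbeta5 are catalytic subunits of the 20S proteasome core. TER94 is the fly p97, an ATPase that extracts ubiquitylated proteins from complexes and membranes. CG6272 encodes a bZIP protein of the C/EBP family. Of the head groups, 3 libraries came from flies whose muscle overexpressed Amyrel, a gene related to amylases, and 3 from driver-only controls. Thorax libraries held 28.9 to 79.2 M reads in genes and head libraries 47.5 to 75.7 M. By group the totals were 31.0 to 32.8 M for GFP RNAi, 31.8 to 32.9 M for white RNAi, 32.1 to 36.1 M for ProsB1 RNAi and 34.4 to 35.7 M for ProsB5 RNAi. They were 28.9 to 31.1 M for Ter94 RNAi, 34.8 to 79.2 M for CG6272 RNAi, 48.8 to 75.7 M for control heads and 47.5 to 70.6 M for Amyrel heads. Levels are given as mean CPM (normalised read counts scaled to library size) ± SD and changes as log2 fold changes ± SE, with n = 3 per group and n = 6 for the pooled controls.

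Some thorax libraries held RNA typical of other organs. The opsin ninaE, the main visual pigment of the outer photoreceptors, stood at 185 and 348 CPM in GFP RNAi replicates 2 and 3 and at 393 CPM in white RNAi replicate 1. It stood at 0.719, 2.49 and 29.6 CPM in the other control libraries, and at 0.215 to 19.2 CPM in the knockdown libraries. The male accessory gland gene Acp36DE stood at 61.7 CPM in GFP RNAi replicate 1, 38.8 CPM in white RNAi replicate 2, 6.72 CPM in white RNAi replicate 1 and 125 CPM in ProsB5 RNAi replicate 1. The counts of genes called in thoraces were therefore also made without the libraries high in Acp36DE, and those that involve a control group without the control libraries high in ninaE, alternatives chosen after the data were seen.

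**Figure D1:**
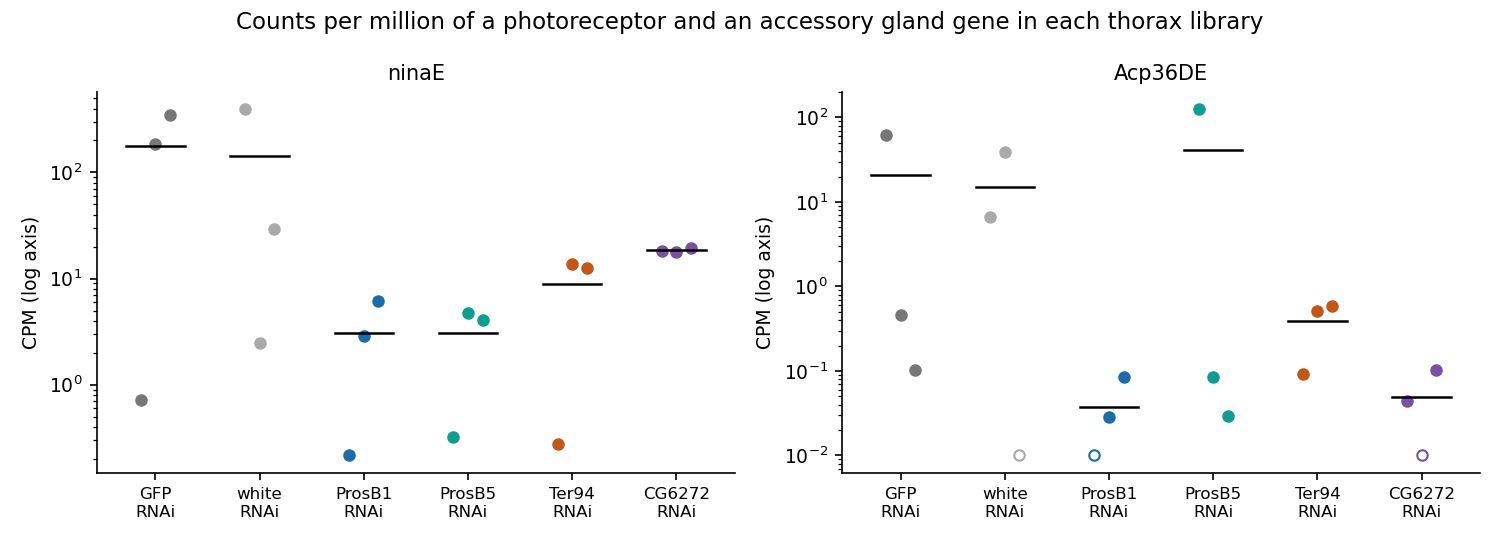
Normalised counts (CPM, log axis) of ninaE, a photoreceptor opsin, and Acp36DE, a male accessory gland gene, in each thorax library, with open points at the axis floor for libraries listed at 0 and a bar at the mean of each group. ninaE lies at 185, 348 and 393 CPM in 3 control libraries, and Acp36DE at 125 CPM in 1 ProsB5 RNAi library.

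How the thorax differs when muscle carries RNAi against Prosbeta1 was asked first. Prosbeta1 fell from 81.1 ± 5.07 CPM in the controls to 42.7 ± 2.9 CPM (log2 -0.93 ± 0.11, adjusted p = 8.82e-05). Amyrel rose from 0.0973 ± 0.0733 to 16.9 ± 9.3 CPM, with 23.7, 6.37 and 20.3 CPM in the 3 knockdown libraries (adjusted p = 5.11e-06). Of the other proteasome core genes 8 of 13 fell, while 9 of 16 genes of starch and maltose breakdown and 12 of 24 of the antimicrobial response rose. Of genes of muscle structure 9 of 32 fell, and of glycolysis 7 of 21. The antimicrobial, muscle and glycolysis lists did not pass against white RNAi alone, and none of these lists passed with an estimated correlation. In edgeR's test 1301 genes rose and 1096 fell of 11262 tested (21.3%).

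Of the 13 measured 20S core members other than the target, 8 fell and 0 rose (12 fell adjusted over the list alone). The list lay lower than other genes (median log2 -0.37, adjusted p = 0.000144 and adjusted p = 0.624 with an estimated correlation). Pros35, an alpha subunit, fell by 0.41 ± 0.10 on the log2 scale (adjusted p = 0.00819, and 0.000137 to 0.102 over its 18 alternatives). Prosbeta5 fell by 0.24 ± 0.06 (adjusted p = 0.00952, and 0.000136 to 0.0833 over its 18 alternatives). None of the 18 regulatory particle (19S) members passed edgeR's test, adjusted over the list alone or not, with 2 lower at an unadjusted p under 0.05 and 2 called by DESeq2. That list had a median of -0.12 (adjusted p = 0.0488, 0.0538 with replicate number in the model, 0.146 against white RNAi alone and adjusted p = 0.801 with an estimated correlation). Of 15 p97 and ubiquitin factors 6 fell and 0 rose (7 fell adjusted over the list alone), with adjusted p = 0.0105 for the list, 0.0569 against white RNAi alone and adjusted p = 0.71 with an estimated correlation. Ubqn, a ubiquilin shuttle factor, fell from 238 ± 12.2 to 194 ± 4.04 CPM (adjusted p = 0.00345).

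Of 16 genes of starch and maltose breakdown and transport, 9 rose and 1 fell, the same counts adjusted over the list alone (median 0.92, adjusted p = 6.81e-08 and adjusted p = 0.612 with an estimated correlation). The maltase Mal-B1 rose from 182 ± 70.6 to 475 ± 43.7 CPM (log2 1.47 ± 0.10, adjusted p = 2.25e-06). Of 9 gut markers 4 rose and 0 fell, also adjusted over the list alone (median -0.14 though the list test leaned higher, adjusted p = 0.00502 and adjusted p = 0.752 with an estimated correlation). Among them the protease gene Jon65Ai, listed at 0 in 5 control libraries and at 0.344 CPM in GFP RNAi replicate 1, stood at 60.5, 15 and 32.9 CPM. The gene mex1 rose from 15.5 ± 4.16 to 34.5 ± 5.56 CPM (adjusted p = 0.000188). Of 24 antimicrobial and immune recognition genes, 12 rose and 2 fell (13 and 2 adjusted over the list alone). The list test gave adjusted p = 0.000976, 0.146 against white RNAi alone and adjusted p = 0.624 with an estimated correlation. The diptericin gene Dpt rose from 4.91 ± 2.82 to 22.2 ± 5.44 CPM (log2 2.35 ± 0.25, adjusted p = 3.52e-05). PGRP-SC2, which encodes a peptidoglycan amidase, rose from 17.8 ± 4.63 to 87.5 ± 41.1 CPM (adjusted p = 4.49e-05). Of 8 haemocyte markers 3 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.131 for the list). Of 10 fat body markers 2 rose and 1 fell (4 and 2 adjusted over the list alone, adjusted p = 0.783). Of 21 ER chaperone genes 7 rose and 1 fell (8 and 1 adjusted over the list alone, adjusted p = 0.0488, 0.127 against GFP RNAi alone and adjusted p = 0.801 with an estimated correlation). Among them was calreticulin, Crc (log2 0.34 ± 0.06, adjusted p = 0.00222).

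Of 32 sarcomere genes 9 fell and 0 rose (11 fell adjusted over the list alone, adjusted p = 0.00115, 0.146 against white RNAi alone and adjusted p = 0.71 with an estimated correlation). The flight muscle gene fln (flightin) fell from 361 ± 97.3 to 154 ± 15.5 CPM (log2 -1.20 ± 0.13, adjusted p = 3.79e-05). The troponin C gene TpnC25D fell by 0.50 ± 0.06 on the log2 scale (adjusted p = 0.000159). Of 21 glycolysis genes 7 fell and 0 rose (12 fell adjusted over the list alone, adjusted p = 0.000373, 0.139 against white RNAi alone and adjusted p = 0.624 with an estimated correlation). They included the hexokinase gene Hex-A (log2 -0.33 ± 0.05, adjusted p = 0.000856). Of 19 secreted factors 5 fell and 0 rose, also adjusted over the list alone (adjusted p = 0.0449, 0.113 against GFP RNAi alone and adjusted p = 0.624 with an estimated correlation). The gene wg, the Wnt ligand Wingless, stood at 2.14 ± 0.196 against 3.85 ± 0.479 CPM (adjusted p = 0.000347). Of 21 autophagy and lysosome genes 6 fell and 0 rose (7 fell adjusted over the list alone, adjusted p = 0.0115 and adjusted p = 0.624 with an estimated correlation). They included the cathepsin gene Cp1 (log2 -0.41 ± 0.04, adjusted p = 2.62e-05) and Atg8a (log2 -0.26 ± 0.05, adjusted p = 0.00222). Of 8 clock genes 5 fell and 0 rose (6 fell adjusted over the list alone, adjusted p = 0.000294, 0.0776 against GFP RNAi alone and adjusted p = 0.0743 with an estimated correlation). They included per (log2 -0.58 ± 0.07, adjusted p = 0.000102). Photoreceptor markers, high in 3 control libraries, were lower, with 11 of 21 called (16 adjusted over the list alone, adjusted p = 0.00137 and adjusted p = 0.821 with an estimated correlation). The heat shock list, with 3 of 20 higher and 0 lower (2 and 0 adjusted over the list alone), had adjusted p = 0.116. The count of called genes was 1089 against both controls separately, 1505 without ProsB1 RNAi replicate 1 and 1530 without the 3 controls high in ninaE.

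RNAi against Prosbeta5 was compared with the same controls. Prosbeta5 fell from 143 ± 8.51 to 69.3 ± 3.45 CPM (log2 -1.05 ± 0.06, adjusted p = 3.81e-07), while 13 of 13 other 20S and 17 of 18 regulatory particle members rose. Rises were called for 13 of 20 heat shock, 22 of 37 glutathione and xenobiotic, 11 of 16 starch and maltose and 16 of 24 antimicrobial genes. Falls were called for 25 of 34 genes of oxidative phosphorylation, 14 of 32 of the sarcomere and 9 of 21 of glycolysis. The glycolysis list did not pass against white RNAi alone, and none of these lists passed with an estimated correlation. Amyrel rose to 22.7 ± 12.4 CPM, at 36.4, 15.8 and 15.4 CPM in the 3 libraries (adjusted p = 2.32e-06). In all, 1943 genes rose and 1549 fell (31.0% of those tested).

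All 13 measured 20S members other than the target rose, also adjusted over the list alone (median 0.45, adjusted p = 1.57e-05 and adjusted p = 0.488 with an estimated correlation). Prosbeta1 rose from 81.1 ± 5.07 to 119.8 ± 22.1 CPM (log2 0.56 ± 0.10, adjusted p = 0.00147). Of the 18 regulatory particle members 17 rose and 0 fell (18 rose adjusted over the list alone, median 0.53, adjusted p = 6e-12 and adjusted p = 0.352 with an estimated correlation). Rpn3 stood at 136 ± 16 against 84.9 ± 7.35 CPM (adjusted p = 0.000116). TER94 rose by 0.41 ± 0.06 on the log2 scale (adjusted p = 0.000181), in a list of p97 and ubiquitin factors of which 8 of 15 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.108). Of 20 heat shock genes 13 rose and 0 fell (14 rose adjusted over the list alone, median 1.43, adjusted p = 3.92e-05 and adjusted p = 0.488 with an estimated correlation). The small heat shock protein gene Hsp23 rose from 9.05 ± 4.26 to 107 ± 80.2 CPM (log2 3.57 ± 0.43, adjusted p = 6.92e-05) and Hsp26 from 47.9 ± 14.2 to 188 ± 82.3 CPM (adjusted p = 0.000598). Of 37 glutathione and xenobiotic genes 22 rose and 3 fell (25 and 3 adjusted over the list alone, adjusted p = 2.78e-06 and adjusted p = 0.352 with an estimated correlation). The glutathione S-transferase gene GstD2 stood at 10.1 ± 4.83 against 1.36 ± 0.593 CPM (adjusted p = 1.49e-05).

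Of the 16 starch and maltose genes 11 rose and 1 fell, also adjusted over the list alone (median 1.37, adjusted p = 7.08e-12 and adjusted p = 0.301 with an estimated correlation). Mal-B1 reached 952 ± 66.8 CPM (log2 2.47 ± 0.10, adjusted p = 2.46e-08). Of 9 gut markers 4 were higher and 0 lower, also adjusted over the list alone (median -0.13 though the list test leaned higher, adjusted p = 0.0114 and adjusted p = 0.507 with an estimated correlation). Of 24 antimicrobial genes 16 rose and 0 fell (17 rose adjusted over the list alone, adjusted p = 1.08e-07 and adjusted p = 0.328 with an estimated correlation). Dpt stood at 18.9 ± 8.83 CPM (adjusted p = 6.44e-05) and PGRP-SD, an immune recognition gene, at 44.5 ± 13.4 against 15.5 ± 3.41 CPM (adjusted p = 9.41e-05). Haemocyte markers moved with this list: all 8 rose, also adjusted over the list alone (adjusted p = 9.35e-06 and adjusted p = 0.124 with an estimated correlation). Hml, a haemocyte clotting protein gene, stood at 345 ± 8.35 against 207 ± 25.8 CPM (adjusted p = 2.37e-05). Of 10 fat body markers 5 rose and 1 fell (6 and 1 adjusted over the list alone, adjusted p = 0.00288 and adjusted p = 0.379 with an estimated correlation). The larval serum protein gene Lsp1beta stood at 826 ± 124 against 302 ± 80.5 CPM (adjusted p = 2.91e-05). Of 21 ER chaperone genes 11 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.00126 and adjusted p = 0.492 with an estimated correlation). Pdi stood at 699 ± 82.3 CPM against 491 ± 40.0 CPM (adjusted p = 0.000321).

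Of 34 oxidative phosphorylation genes 25 fell and 0 rose (30 fell adjusted over the list alone, 9 fell against each control separately, median -0.31, adjusted p = 5.42e-08 and adjusted p = 0.488 with an estimated correlation). The cytochrome c oxidase subunit gene cype fell from 718 ± 44.6 to 562 ± 44.4 CPM (log2 -0.35 ± 0.07, adjusted p = 0.00152, and up to 0.0626 over its alternatives). Of 32 sarcomere genes 14 fell and 1 rose (16 and 1 adjusted over the list alone, adjusted p = 2.12e-05 and adjusted p = 0.492 with an estimated correlation). The troponin C gene TpnC4 stood at 369 ± 30.7 against 723 ± 261 CPM (adjusted p = 2.74e-05). The control lines themselves differed in TpnC4, which was lower in white than in GFP RNAi. Of 21 glycolysis genes 9 fell and 0 rose (12 fell adjusted over the list alone, adjusted p = 0.000523, 0.0996 against white RNAi alone and adjusted p = 0.492 with an estimated correlation). Ald, the aldolase gene, stood at 5909 ± 495 against 8651 ± 1509.9 CPM (adjusted p = 0.000379). Clock genes were lower, 4 of 8 with 0 higher, also adjusted over the list alone (adjusted p = 0.00288, 0.259 against GFP RNAi alone and adjusted p = 0.124 with an estimated correlation). The gene vri stood at 195 ± 29 against 291 ± 32.1 CPM (adjusted p = 0.000913, and up to 0.052 over its alternatives). Photoreceptor markers were lower in 18 of 21 cases (20 adjusted over the list alone, adjusted p = 0.000339 and adjusted p = 0.554 with an estimated correlation). In the list of ATF4 and C/EBP stress genes, 7 of 21 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.355). The calls numbered 1735 against both controls separately, 2274 without the 3 controls high in ninaE and 1714 without the 4 libraries high in Acp36DE.

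The difference between the proteasome knockdowns was tested directly, with no control library in the contrast, though the shared fit takes its spread from the controls too. In ProsB5 RNAi all 12 other 20S members (median 0.83, adjusted p = 3.34e-33 and adjusted p = 0.0294 with an estimated correlation) and all 18 regulatory particle members (median 0.66, adjusted p = 1.89e-43 and adjusted p = 0.0294 with an estimated correlation) stood above ProsB1 RNAi, also adjusted over the list alone. Pros35 stood at 101 ± 13.8 against 56 ± 1.02 CPM (log2 0.85 ± 0.11, adjusted p = 0.000902), and the 19S ATPase gene Tbp-1 at 126 ± 19.8 against 75.9 ± 3.16 CPM (adjusted p = 0.00139). The targets themselves lay apart in opposite directions, Prosbeta1 by 1.49 ± 0.13 and Prosbeta5 by -0.80 ± 0.07 (adjusted p = 6.24e-05 for each). Rpt6R and Rpt3R, which encode paralogues of 19S ATPases and are on none of the lists, stood at 6.86 ± 3.67 and 10.5 ± 9.49 CPM against 0.358 ± 0.203 and 0.592 ± 0.126 CPM (adjusted p = 0.000902 and 0.00187). In all, 384 genes were higher in ProsB5 RNAi and 288 lower (5.97%).

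Of 15 p97 and ubiquitin factors 7 were higher and 1 lower in ProsB5 RNAi (10 and 1 adjusted over the list alone, adjusted p = 1.14e-10 and adjusted p = 0.187 with an estimated correlation). TER94 stood at 474 ± 39.1 against 334 ± 7.63 CPM (adjusted p = 0.00101). Of 37 glutathione genes 7 were higher and 0 lower (10 higher adjusted over the list alone, adjusted p = 7.15e-08 and adjusted p = 0.242 with an estimated correlation). GstE1 stood at 137 ± 10.3 against 56.5 ± 3.88 CPM (adjusted p = 0.000911). Of 20 heat shock genes 3 were higher and 0 lower, also adjusted over the list alone (adjusted p = 8.82e-05 and adjusted p = 0.342 with an estimated correlation), with Hsp23 higher by 3.25 ± 0.55 (adjusted p = 0.00429). Mal-B1 (log2 1.00 ± 0.12, adjusted p = 0.000694) and Mal-B2 (log2 0.95 ± 0.12, adjusted p = 0.000902) were the 2 called starch and maltose genes, with 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.00737 and adjusted p = 0.393 with an estimated correlation). Amyrel did not pass the test (log2 0.43 ± 0.44, adjusted p = 0.692). Of 24 antimicrobial genes 2 were higher and 0 lower (3 higher adjusted over the list alone, adjusted p = 0.00128 and adjusted p = 0.342 with an estimated correlation). Beside them 3 of 8 haemocyte markers were higher and 0 lower (6 higher adjusted over the list alone, adjusted p = 6.18e-06 and adjusted p = 0.232 with an estimated correlation). So were 4 of 10 fat body markers, with 0 lower (5 higher adjusted over the list alone, adjusted p = 9.85e-05 and adjusted p = 0.262 with an estimated correlation). Of 34 oxidative phosphorylation genes 3 were lower and 0 higher (10 lower adjusted over the list alone, median -0.22, adjusted p = 2.17e-10 and adjusted p = 0.342 with an estimated correlation). Of 19 secreted factors 3 were higher and 0 lower (5 higher adjusted over the list alone, adjusted p = 0.00825 and adjusted p = 0.333 with an estimated correlation). The cytokine gene upd3 stood at 0.713 ± 0.115 against 0.232 ± 0.0473 CPM (adjusted p = 0.00912). Replicate numbers were taken to pair these libraries, and with replicate number in the model the fold changes of l(2)efl, slbo and ND23 no longer passed (adjusted p = 0.053, 0.0612 and 0.0512, and up to 0.187, 0.23 and 0.249 over all their alternatives). The genes v and per passed with it (adjusted p = 0.0494 and 0.0437, against 0.0528 and 0.0647 without it, and 0.00979 to 0.303 and 0.0414 to 0.219 over their alternatives). The count of 672 became 327 in a fit of these 2 groups alone, 300 without the 4 libraries high in Acp36DE, 374, 385 and 371 without ProsB1 RNAi replicate 1, 2 or 3, and 417 without ProsB5 RNAi replicate 2.

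**Figure D2:**
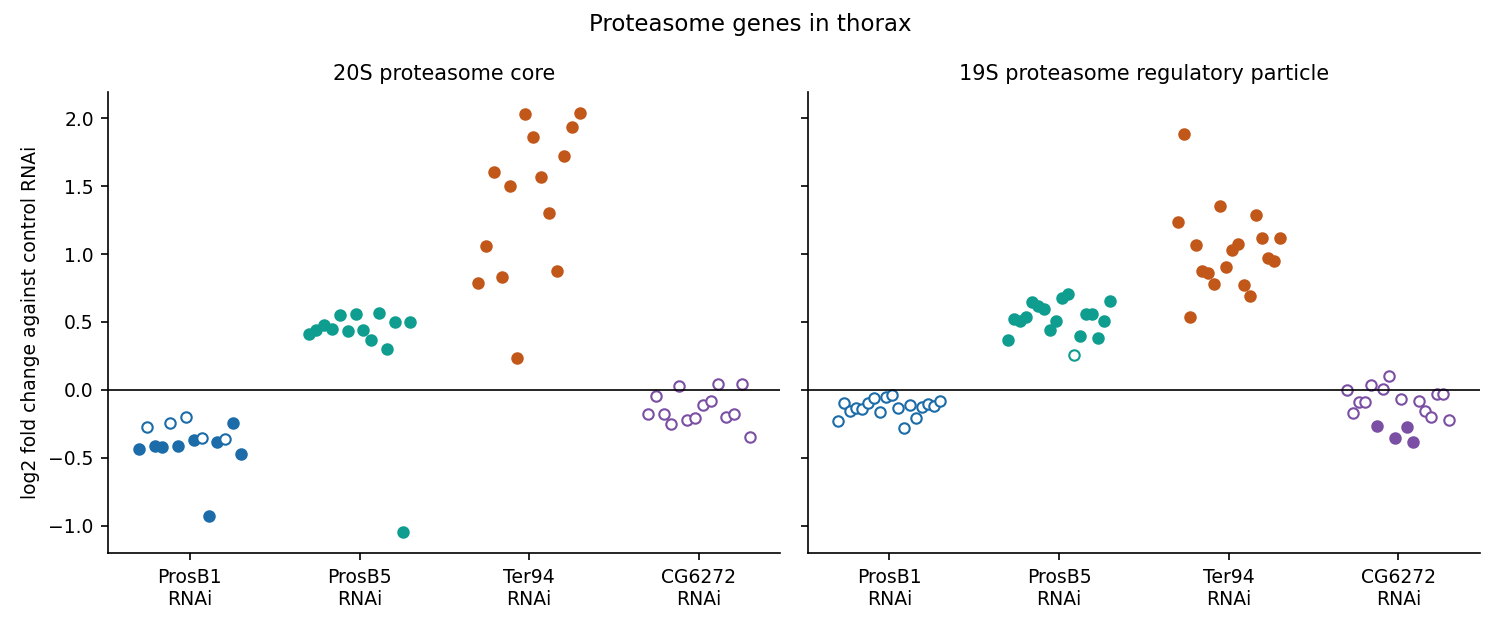
Log2 fold change against the control RNAi thoraces of each measured 20S core and 19S regulatory particle gene in the ProsB1, ProsB5, Ter94 and CG6272 knockdowns, 1 point per gene with targets included, filled where the adjusted p lies under 0.05. The medians without the target under ProsB1, ProsB5 and Ter94 RNAi were -0.37, 0.45 and 1.54 for the 20S core and -0.12, 0.53 and 1.00 for the 19S particle. Under CG6272 RNAi they were -0.18 and -0.09.

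More genes were called for RNAi against Ter94 than for either proteasome knockdown. TER94 fell from 358 ± 27 to 235 ± 0.848 CPM (log2 -0.61 ± 0.06, adjusted p = 2.51e-06). All measured proteasome genes of the lists rose, and all 34 genes of oxidative phosphorylation and 18 of 21 of glycolysis fell, though none of these lists passed with an estimated correlation. The glutathione transferase gene GstD9 rose, and the flight muscle genes fln and TpnC4 fell. In all, 3347 genes rose and 3197 fell (58.1%), of which 2203 and 2371 passed against each control separately.

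All 14 core proteasome members (median 1.54, adjusted p = 5.5e-21 and adjusted p = 0.171 with an estimated correlation) and all 18 regulatory particle members (median 1.00, adjusted p = 5.67e-19 and adjusted p = 0.183 with an estimated correlation) rose, also adjusted over the list alone. Prosbeta5 rose from 143 ± 8.51 to 548 ± 29.5 CPM (log2 1.93 ± 0.05, adjusted p = 1.35e-10), and the 19S gene Mov34 from 91.5 ± 6.81 to 338 ± 34.2 CPM (adjusted p = 6.22e-09). Of 14 p97 and ubiquitin factors other than the target 10 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.00159 and adjusted p = 0.608 with an estimated correlation). Ufd1-like, a p97 cofactor gene, rose by 1.61 ± 0.09 on the log2 scale (adjusted p = 2.33e-08). Of 20 heat shock genes 10 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.015 and adjusted p = 0.788 with an estimated correlation). Hsp23 stood at 376 ± 142 CPM (log2 5.38 ± 0.45, adjusted p = 6.84e-07). Glutathione genes went both ways, 13 of 37 higher and 15 lower (13 and 16 adjusted over the list alone, median -0.06 though the list test leaned higher, adjusted p = 0.205). GstD9 stood at 579 ± 72 against 45.2 ± 8.4 CPM (log2 3.69 ± 0.09, adjusted p = 2.24e-11). In the ATF4 and C/EBP list 6 of 21 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.136). Gadd45 stood at 90.5 ± 4.37 against 24.3 ± 4.2 CPM (adjusted p = 3e-08) and CG6272 itself higher by 0.42 ± 0.07 (adjusted p = 0.000335).

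All 34 oxidative phosphorylation genes fell, also adjusted over the list alone (median -0.73, adjusted p = 2.05e-13 and adjusted p = 0.352 with an estimated correlation). Among them were cype (log2 -0.93 ± 0.07, adjusted p = 2.49e-07) and ND23, a complex I subunit gene (log2 -0.71 ± 0.05, adjusted p = 3.28e-07). Of 21 glycolysis genes 18 fell and 0 rose, also adjusted over the list alone (median -0.57, adjusted p = 8.39e-08 and adjusted p = 0.352 with an estimated correlation). Hex-A stood at 434 ± 11.3 against 759 ± 80.2 CPM (adjusted p = 1.51e-07). The sarcomere list went both ways, with 3 of 32 higher and 10 lower (3 and 9 adjusted over the list alone, adjusted p = 0.201). In it fln fell from 361 ± 97.3 to 20.7 ± 1.92 CPM (log2 -4.10 ± 0.16, adjusted p = 1.55e-09) and TpnC4 to 83.6 ± 5.27 CPM (adjusted p = 7.88e-10). The actin gene Act57B rose by 0.87 ± 0.07 (adjusted p = 7.58e-07). Among secreted factors 8 of 19 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.366). The peptide hormone gene CCHa2 stood at 302 ± 10.8 against 147 ± 24.1 CPM (adjusted p = 5.03e-07) and upd3 at 2.21 ± 0.165 against 0.374 ± 0.179 CPM (adjusted p = 1.66e-06). Amyrel rose to 9.39 ± 1.67 CPM (adjusted p = 1.45e-06), in a list of which 6 of 16 rose and 9 fell, also adjusted over the list alone (adjusted p = 0.311). Gut markers also split, with 3 of 9 higher and 6 lower, also adjusted over the list alone (adjusted p = 0.631). The abundant trypsin gene alphaTry stood at 2585 to 2818 CPM in the controls and at 42.7, 539 and 579 CPM in the 3 knockdown libraries. Haemocyte markers were lower, 6 of 8 with 0 higher, also adjusted over the list alone (adjusted p = 0.049, 0.0623 with replicate number in the model and adjusted p = 0.77 with an estimated correlation). So were 6 of 7 glial markers with 0 higher, also adjusted over the list alone (adjusted p = 0.107). Of 21 photoreceptor markers 14 were lower and 1 higher (16 and 1 adjusted over the list alone, median -3.46, adjusted p = 0.46). Of 12 neuron markers 8 were higher and 1 lower (9 and 1 adjusted over the list alone, adjusted p = 0.376), and of 10 fat body markers 2 were lower and 0 higher (1 lower adjusted over the list alone, adjusted p = 0.966). The eye pigment transporter gene w, which many transgenes carry as a marker, stood at 76.8 ± 5.26 against 1.64 ± 0.137 CPM (adjusted p = 1.78e-12). It was 1 of 2 higher members of a 6-gene list with 1 lower, also adjusted over the list alone (median -0.09 though the list test leaned higher, adjusted p = 0.00159 and adjusted p = 0.171 with an estimated correlation). Replicates 2 and 3 of Ter94 RNAi were closer to each other than any other pair, with a scaled chi-square per gene of 1.76 against at least 11.9 elsewhere. With the 2 summed as 1 library 5815 genes were called in place of 6544.

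Ter94 RNAi was also set against the 2 proteasome knockdowns directly. The reference was the mean of these 2 knockdowns, in which core proteasome genes had moved in opposite directions from the controls. Against it proteasome genes stood higher, 11 of 12 core members with 0 lower (12 higher adjusted over the list alone, median 1.46, adjusted p = 4.82e-15 and adjusted p = 0.23 with an estimated correlation) and all 18 regulatory particle members, also adjusted over the list alone (median 0.79, adjusted p = 1.54e-13 and adjusted p = 0.357 with an estimated correlation). All 16 starch and maltose genes stood lower, also adjusted over the list alone (median -1.90, adjusted p = 4.19e-06 and adjusted p = 0.36 with an estimated correlation). Mal-B1 stood at 286 ± 4.51 against 714 ± 266 CPM (adjusted p = 1.53e-06). Gut markers moved with them, 7 of 9 lower and 0 higher, also adjusted over the list alone (adjusted p = 0.0245 and adjusted p = 0.659 with an estimated correlation), with mex1 lower by 3.00 ± 0.20 in log2 terms, at 4.69 ± 0.444 against 37.6 ± 8.23 CPM (adjusted p = 1.23e-07). Of 34 oxidative phosphorylation genes 31 were lower and 0 higher, also adjusted over the list alone (median -0.53, adjusted p = 7.81e-08 and adjusted p = 0.576 with an estimated correlation). Of 21 glycolysis genes 17 were lower and 0 higher (18 lower adjusted over the list alone, adjusted p = 0.000636 and adjusted p = 0.587 with an estimated correlation). The glutathione S-transferase gene GstD9 stood at 579 ± 72 against 40.6 ± 5.8 CPM (log2 3.84 ± 0.09, adjusted p = 8.6e-12), in a list of 37 with 10 higher and 19 lower (median -0.17). Gadd45 stood at 90.5 ± 4.37 against 22.5 ± 0.952 CPM (adjusted p = 2.47e-08), in a list of 21 with 7 higher and 4 lower. The antifungal peptide gene Drs stood lower by -1.59 ± 0.18 (adjusted p = 8.86e-06), in a list of 24 with 1 higher and 7 lower, also adjusted over the list alone (adjusted p = 0.376). Haemocyte markers were lower in 7 of 8 cases with 0 higher, also adjusted over the list alone (adjusted p = 2.39e-05 and adjusted p = 0.278 with an estimated correlation). Glial markers were lower in 6 of 7 cases and fat body markers in 4 of 10, with 0 higher, also adjusted over the list alone (adjusted p = 0.0923 and 0.326). Neuron markers were higher in 8 of 12 cases and lower in 1, also adjusted over the list alone (adjusted p = 0.14), and 1 of 21 photoreceptor markers was higher with 0 lower, also adjusted over the list alone (adjusted p = 0.326). In all, 3090 genes were higher and 3335 lower (57.1%), and 4784 passed against each proteasome knockdown separately. With Ter94 RNAi replicates 2 and 3 summed as 1 library the count was 5692.

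RNAi against CG6272 was compared with the controls in a fit of 9 libraries, since its library titles have another form and no control shares it, so that library batch and genotype cannot be separated. CG6272 fell from 26.7 ± 1.25 to 14 ± 0.89 CPM (log2 -0.94 ± 0.07, adjusted p = 0.000158). Amyrel rose from 0.0932 ± 0.0702 to 3.62 ± 1.29 CPM (adjusted p = 0.000461), and Jon65Ai stood at 26.2, 29.3 and 17.2 CPM (adjusted p = 0.000411). Of 20 heat shock genes 13 fell and of 34 oxidative phosphorylation genes 10 rose, but 2 and 1 of these passed against each control separately, and neither list passed with an estimated correlation. In all, 1435 genes rose and 1028 fell of 10784 tested (22.8%).

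Of 20 heat shock genes 13 fell and 1 rose, also adjusted over the list alone (median -0.71, adjusted p = 0.00128 and adjusted p = 0.861 with an estimated correlation), and 2 of the falls passed against each control separately. Hsp70Aa stood at 3.32 ± 0.572 against 40.9 ± 29.1 CPM (log2 -3.61 ± 0.76, adjusted p = 0.0135). Of 34 oxidative phosphorylation genes 10 rose and 0 fell (16 rose adjusted over the list alone, median 0.45, adjusted p = 5.44e-05 and adjusted p = 0.861 with an estimated correlation), of which 1 passed against each control. ND23 rose from 656 ± 29.4 to 1099 ± 283 CPM (log2 0.74 ± 0.14, adjusted p = 0.00761, and up to 0.166 over its alternatives). Of 16 starch and maltose genes 7 rose and 3 fell (8 and 3 adjusted over the list alone, adjusted p = 0.0133, 0.224 against white RNAi alone and adjusted p = 0.861 with an estimated correlation). Mal-B2 stood at 305 ± 14.7 against 185 ± 32.3 CPM (adjusted p = 0.000779, and up to 0.0571 over its alternatives). Gut markers split 3 higher and 1 lower of 9, also adjusted over the list alone (adjusted p = 0.545). Of 24 antimicrobial genes 7 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.00128, 0.224 against white RNAi alone and adjusted p = 0.861 with an estimated correlation). PGRP-SC2 stood at 31.2 ± 2.5 against 17.1 ± 4.47 CPM (adjusted p = 0.000774). Of the haemocyte markers 4 of 8 fell and 0 rose (6 fell adjusted over the list alone, adjusted p = 0.0182, 0.222 against GFP RNAi alone and adjusted p = 0.799 with an estimated correlation). None of the 14 core proteasome members passed edgeR's test, adjusted over the list alone or not, with 1 lower at an unadjusted p under 0.05 and 1 by DESeq2. Of the regulatory particle members 4 of 18 fell with 0 higher, also adjusted over the list alone (adjusted p = 0.0965 for the list).

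Single genes of other lists moved as well. The selective autophagy receptor gene ref(2)P fell from 523 ± 46.3 to 366 ± 17.7 CPM (adjusted p = 0.00276, and up to 0.162 over its alternatives). Its list of 21 had 5 lower and 1 higher, also adjusted over the list alone (adjusted p = 0.0965). ImpL2, which encodes a secreted binder of insulin-like peptides, fell from 199 ± 27.3 to 111 ± 6.12 CPM (adjusted p = 0.00341, and up to 0.0578 over its alternatives). In all 4 of 19 secreted factors fell and 2 rose (6 and 2 adjusted over the list alone, adjusted p = 0.236). In the ATF4 and C/EBP list without the target, 3 of 20 rose and 1 fell (3 and 6 adjusted over the list alone, adjusted p = 0.826). Its members CG5840 and CG3011 rose by 0.74 ± 0.08 and 0.70 ± 0.09 (adjusted p = 0.000935 and 0.00138, and up to 0.0552 and 0.127 over their alternatives). The fat body gene to fell from 124 ± 17.5 to 40.8 ± 5.77 CPM (adjusted p = 8.86e-05), in a list of 10 with 3 higher and 2 lower, also adjusted over the list alone (adjusted p = 0.874). Of the 57 named genes called here 17 kept their call without the 3 controls high in ninaE. The count of 2463 was 828 against both controls separately, 299 without the 3 controls high in ninaE, 341 without the 3 of these libraries high in Acp36DE, 1246 against white RNAi alone and 4328 in a fit of all thorax libraries. It was 1439 without GFP RNAi replicate 2 and 1428, 1239 and 1220 without white RNAi replicate 1, 2 or 3.

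The control lines were compared with each other as a background. The libraries labelled white RNAi held w at 1.74 ± 0.127 CPM against 1.54 ± 0.0234 CPM in GFP RNAi (log2 0.18 ± 0.14, adjusted p = 0.529). The protease gene CG11313 stood at 61.3 ± 1.93 against 0.164 ± 0.0529 CPM (log2 8.50 ± 0.18, adjusted p = 1.36e-11). The gene y, needed for black cuticle pigment, stood at 0.0881 ± 0.0963 against 24.5 ± 3.59 CPM (adjusted p = 2.61e-07). The clock gene tim stood at 253 ± 14.9 against 118 ± 8.37 CPM (adjusted p = 1.54e-06). In all 2 of 8 clock genes were higher and 0 lower, also adjusted over the list alone (adjusted p = 0.00198 and adjusted p = 0.136 with an estimated correlation). Lsp2, a serum protein gene of the fat body, stood at 673 ± 122 against 97.4 ± 46.1 CPM (adjusted p = 0.000926). In all, 765 genes were higher in white RNAi and 686 lower (12.9%).

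Of 37 glutathione and xenobiotic genes 9 were higher and 2 lower (10 and 2 adjusted over the list alone, adjusted p = 0.00016 and adjusted p = 0.432 with an estimated correlation). The cytochrome P450 gene Cyp6a2 stood at 153 ± 1.43 against 35.5 ± 7.38 CPM (adjusted p = 2.61e-07). Of 21 ATF4 and C/EBP genes 9 were higher and 3 lower (10 and 3 adjusted over the list alone, adjusted p = 0.00928 and adjusted p = 0.432 with an estimated correlation). The gene asparagine-synthetase stood at 82 ± 17.1 against 40.4 ± 1.86 CPM (adjusted p = 0.000862). Of 24 antimicrobial genes 6 were higher and 0 lower (7 higher adjusted over the list alone, adjusted p = 0.000437 and adjusted p = 0.432 with an estimated correlation). Beside them 3 of 8 haemocyte markers were higher and 0 lower, also adjusted over the list alone (adjusted p = 0.0589). Of 21 glycolysis genes 9 were lower and 0 higher (10 lower and 2 higher adjusted over the list alone, adjusted p = 0.00016 and adjusted p = 0.546 with an estimated correlation). Of 32 sarcomere genes 5 were lower and 0 higher, also adjusted over the list alone (adjusted p = 0.000437 and adjusted p = 0.71 with an estimated correlation). TpnC4 stood at 497 ± 26.2 against 948 ± 132 CPM (adjusted p = 0.00012). Of 14 JNK and cell death genes 3 were higher and 0 lower, also adjusted over the list alone (adjusted p = 0.0434, 0.0503 with replicate number in the model and adjusted p = 0.432 with an estimated correlation). Amyrel did not pass the test (adjusted p = 0.859), but of the 16 starch and maltose genes 3 were higher and 1 lower (median 0.47). In edgeR's test none of the 14 core proteasome, 18 regulatory particle and 21 photoreceptor genes passed, adjusted over the list alone or not, with 0 in each at an unadjusted p under 0.05 and 0 by DESeq2. The count of 1451 was 828 and 906 without white RNAi replicate 2 or 3. Counts without the 3 libraries high in ninaE, or the 3 of these libraries high in Acp36DE, are not given. They leave only GFP RNAi replicate 1, or only white RNAi replicate 3, in a compared group.

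Calls overlapped between knockdowns. ProsB1 and ProsB5 RNAi shared 1704 genes called in the same direction and 46 in opposite directions, against 375 expected of independent lists. ProsB1 and CG6272 RNAi shared 1026 with 38 opposite, and ProsB5 and CG6272 RNAi 1215 with 126 opposite, against 273 and 400.5 expected. Ter94 RNAi shared 1119 with ProsB1 RNAi and 1785 with ProsB5 RNAi, with 547 and 647 opposite, against 698 and 1017 expected. With CG6272 RNAi it shared 1303 with 417 opposite, against 732 expected, and 692 or 791 with a different control for each. All of these share the control libraries. With GFP RNAi as the control of 1 knockdown and white RNAi of the other, ProsB1 and ProsB5 RNAi shared 1097 or 951, ProsB1 and CG6272 RNAi 524 or 570, ProsB5 and CG6272 RNAi 582 or 718, and Ter94 RNAi 829 or 779 with ProsB1 and 1314 or 1282 with ProsB5 RNAi. Across genes, which are not independent replicates, log2 fold changes of ProsB1 and ProsB5 RNAi had a Pearson correlation of 0.679. With CG6272 RNAi it was 0.883 for ProsB1, 0.639 for ProsB5 and 0.630 for Ter94 RNAi. Ter94 RNAi gave 0.623 with ProsB1 and 0.482 with ProsB5 RNAi. Unchanged groups simulated against the shared controls had a mean of 0.114. That simulation held no differences between lines, so it does not bound what the shared controls alone can give. Of 10775 genes tested in both fits 221 rose and 335 fell in all 4 knockdowns, and 84 and 152 did so against each control separately.

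Heads with Amyrel driven in muscle were compared with driver-only heads. Amyrel rose from 0.0918 ± 0.0302 to 7.04 ± 0.193 CPM (log2 6.19 ± 0.16, adjusted p = 6.84e-06). Heat shock genes were the list with the smallest list p (adjusted p = 4.11e-24), but did not pass with an estimated correlation (adjusted p = 0.437). The defensin gene Def rose from 2.16 ± 0.691 to 9.2 ± 0.259 CPM (log2 2.07 ± 0.20, adjusted p = 0.00471). The gene mthl8, which encodes a methuselah-like receptor, fell from 64.7 ± 4.17 to 16.3 ± 1.74 CPM (adjusted p = 0.000183). In all, 85 genes rose and 77 fell of 10748 tested (1.51%), with 1513 at an unadjusted p under 0.05.

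Of 20 heat shock genes 6 rose and 0 fell (16 rose adjusted over the list alone, median 1.37, adjusted p = 4.11e-24 and adjusted p = 0.437 with an estimated correlation). Hsp23 stood at 1452, 484 and 190 CPM in the Amyrel heads against 23.7, 25.9 and 28.7 CPM in the control heads (log2 4.77 ± 0.71, adjusted p = 0.0236). Hsp68 stood at 1551, 572 and 302 CPM against 82.2, 109 and 103 CPM (log2 3.05 ± 0.55, adjusted p = 0.0469). Hsp70Ba, Hsp70Bb, Hsp70Ab and Hsp70Bbb, near-identical copies among which reads are hard to place, were higher by 2.62 ± 0.48, 1.61 ± 0.25, 1.26 ± 0.20 and 1.81 ± 0.30 (adjusted p = 0.0469, 0.0294, 0.0329 and 0.0351). Hsp70Bbb was named after its values were seen, to complete the 6, and was not examined under the alternatives. Replicate numbers were taken to pair the head libraries, and with replicate number in the model Hsp23, Hsp68, Hsp70Ba, Hsp70Bb and Hsp70Ab no longer passed (adjusted p = 0.0532, 0.103, 0.118, 0.0748 and 0.0559). Hsp23 had adjusted p = 0.0757, 0.126 and 0.0929 without control replicate 1, 2 or 3, 0.00631, 0.0844 and 0.00916 without Amyrel replicate 1, 2 or 3, and Hsp68 0.124, 0.186, 0.149, 0.0139, 0.123 and 0.0239 in the same order. Hsp70Ba, Hsp70Bb and Hsp70Ab lost their calls without control replicate 2 or 3 or Amyrel replicate 2, and Hsp70Bb also without control replicate 1 and Hsp70Ba and Hsp70Ab also without Amyrel replicate 1 or 3 (adjusted p from 0.0518 to 0.144).

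**Figure D3:**
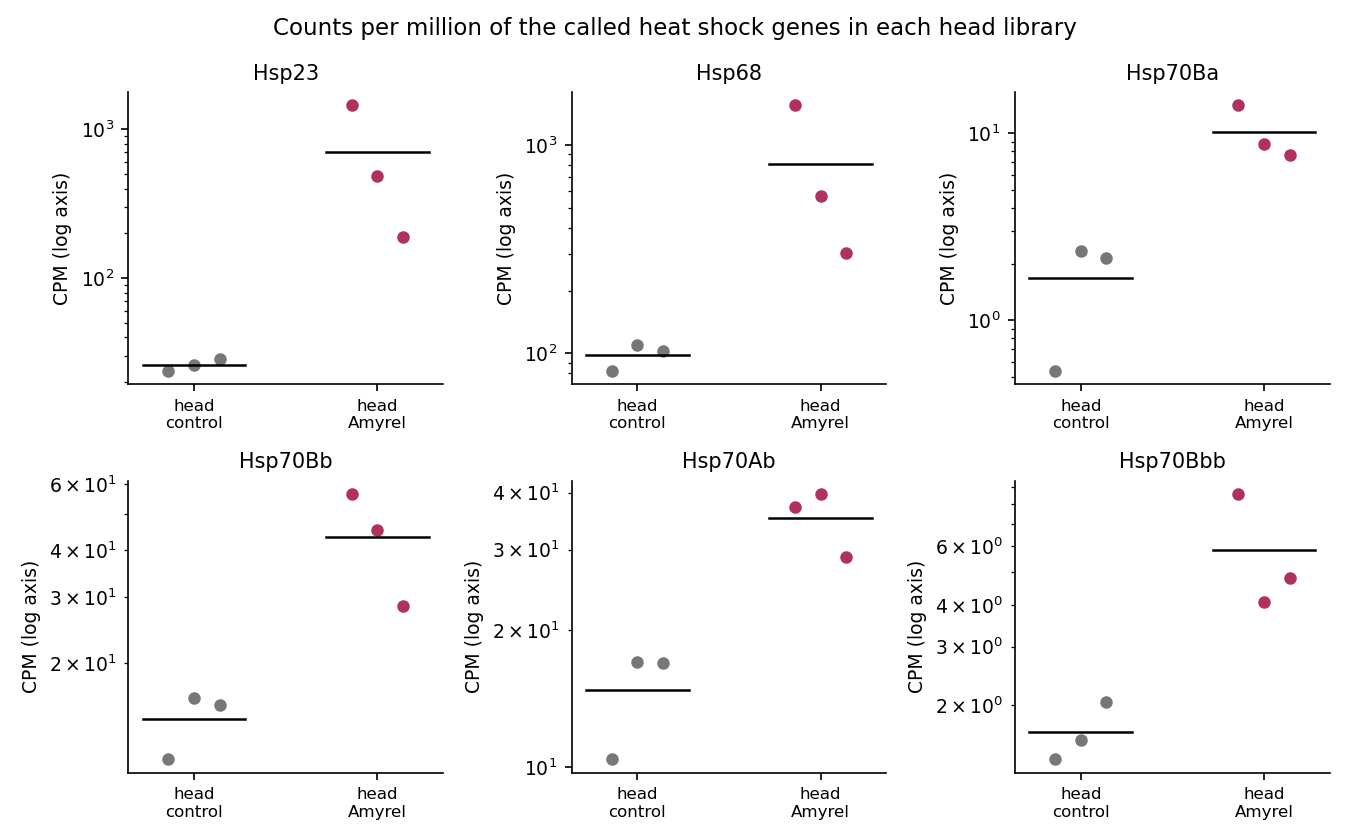
Normalised counts (CPM, log axis) of the 6 heat shock genes called in heads, in each control and Amyrel head library, with a bar at the mean of each group. Every Amyrel head lies above every control head, with Hsp23 at 1452, 484 and 190 CPM against 23.7 to 28.7 CPM.

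Of 24 antimicrobial genes 3 rose and 0 fell in heads (6 rose adjusted over the list alone, median 0.45, adjusted p = 1.36e-06 and adjusted p = 0.523 with an estimated correlation). Besides Def these were PGRP-SD and Drs, at 24.8 ± 7.22 against 8.46 ± 0.167 CPM (adjusted p = 0.0169, and 0.0525, 0.0895 and 0.066 without control replicate 1, 2 or 3 and 0.0844 without Amyrel replicate 2). PGRP-SD stood at 28.4 ± 1.88 against 16.3 ± 3.52 CPM (adjusted p = 0.0459, and 0.066 to 0.166 without any 1 library other than control replicate 2). In the list of 37 glutathione genes se fell (adjusted p = 0.0187, and 0.061 to 0.0925 without control replicate 2 or 3 or Amyrel replicate 2 or 3) and 0 rose (1 lower and 7 higher adjusted over the list alone). The list lay higher than other genes (median 0.15, adjusted p = 3.8e-05 and adjusted p = 0.523 with an estimated correlation). GstE1 stood at 193 ± 32.1 against 119 ± 17.3 CPM (adjusted p = 0.0605, 0.00642 with replicate number in the model and up to 0.258 over its alternatives). No 19S member passed edgeR's test, adjusted over the list alone or not, with 9 of 18 higher at an unadjusted p under 0.05 and 0 by DESeq2. The list had a median of 0.11 (adjusted p = 0.00026 and adjusted p = 0.552 with an estimated correlation). No 20S member passed either, adjusted over the list alone or not, with 1 of 13 higher at an unadjusted p under 0.05 and 0 by DESeq2 (adjusted p = 0.0292, 0.0768 with replicate number in the model and adjusted p = 0.784 with an estimated correlation). No ER chaperone gene passed over all genes, with 2 of 21 higher adjusted over the list alone, 5 at an unadjusted p under 0.05 and 3 by DESeq2 (median 0.10, adjusted p = 0.000529 and adjusted p = 0.523 with an estimated correlation). The eye pigment transporter gene w stood at 22.7 ± 0.655 against 9.77 ± 0.552 CPM (log2 1.22 ± 0.06, adjusted p = 0.000191). Its list of 7 had 1 higher and 0 lower (1 and 1 adjusted over the list alone, adjusted p = 0.0227 and adjusted p = 0.446 with an estimated correlation). Of 21 photoreceptor genes, trpl, a light-activated channel gene, was lower (log2 -0.41 ± 0.07, adjusted p = 0.0428, 0.0639 with replicate number in the model and 0.0705 to 0.147 without any 1 library) and 0 were higher (4 higher and 2 lower adjusted over the list alone, adjusted p = 0.637). Of 8 clock genes Clk was higher (log2 0.42 ± 0.07, adjusted p = 0.0272, 0.0532 with replicate number in the model and 0.0674 to 0.15 without any 1 library other than Amyrel replicate 1) and 0 were lower (1 higher and 4 lower adjusted over the list alone, adjusted p = 0.125). The clock gene tim stood at 375 ± 129 against 735 ± 139 CPM (adjusted p = 0.118, 0.0198 with replicate number in the model and up to 0.318 over its alternatives). The ionotropic receptor gene Ir75b fell from 23.5 ± 1.94 to 9.97 ± 1.14 CPM (adjusted p = 0.00181). GstE3 and Hsc70-3, an ER chaperone gene, passed with replicate number in the model but not without it (adjusted p = 0.0434 and 0.0468, against 0.0961 and 0.112, and 0.000311 to 0.315 and 0.00293 to 0.389 over their alternatives, the lowest by DESeq2). The troponin C gene TpnC41C was lower (log2 -0.38 ± 0.05, adjusted p = 0.0193), but not with replicate number in the model (adjusted p = 0.0532) or without control replicate 1, 2 or 3 (adjusted p = 0.0525, 0.0977 and 0.0665) or Amyrel replicate 2 or 3 (adjusted p = 0.0525 and 0.0675; 4.58e-05 to 0.0977 over its alternatives). In the neuron list of 12 and the oxidative phosphorylation list of 34, none passed edgeR's test, adjusted over the list alone or not, and 0 passed at an unadjusted p under 0.05 or by DESeq2 (adjusted p = 0.637 and 0.649 for the lists). Without 1 library the count of 162 was 25 (without Amyrel replicate 2), 82 (Amyrel replicate 3), 105, 27 and 60 (control replicates 1, 2 and 3). 

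**Figure D4:**
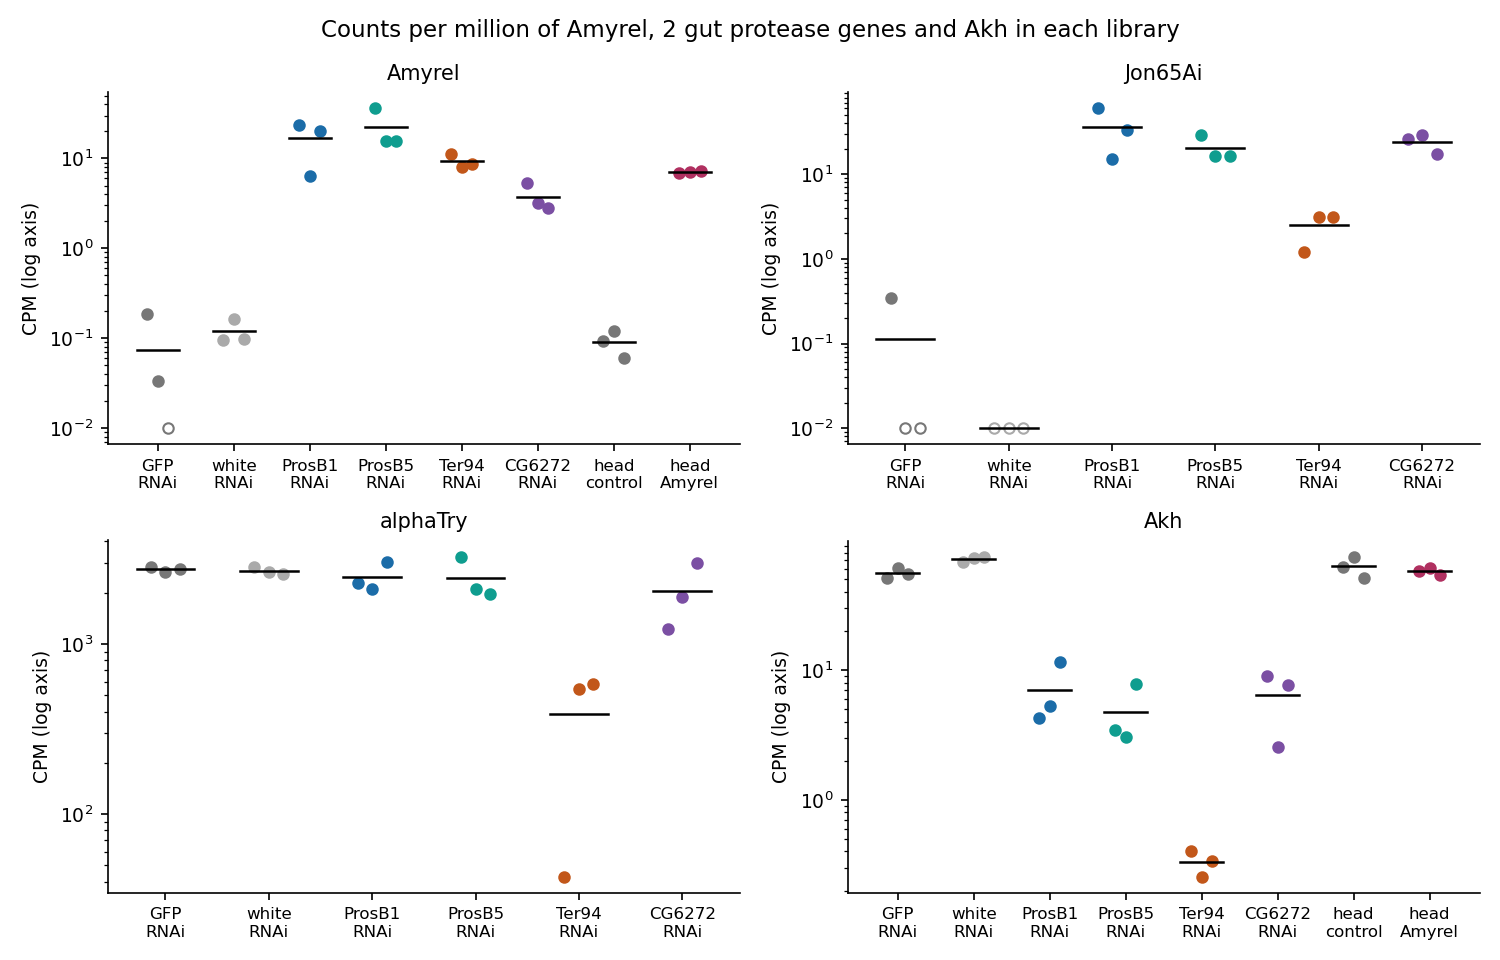
Normalised counts (CPM, log axis) per library of Amyrel and the hormone gene Akh in all groups and of the gut protease genes Jon65Ai and alphaTry in the thorax groups, with open points at the axis floor for libraries listed at 0 and a bar at the mean of each group. Amyrel lies at 2.84 to 36.4 CPM in the knockdown thoraces and at no more than 0.187 CPM in the control thoraces.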

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

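The tests of explanations and the splits in this part were chosen after the results were seen, apart from the test of neighbouring genes between the control lines; the comparison of ProsB5 with ProsB1 RNAi and the model with replicate number were not.

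In heads with muscle-driven Amyrel, heat shock genes stood higher than in control heads. Of the 6 called genes, the 5 examined with replicate number in the model all failed to pass with it (adjusted p = 0.0532 to 0.118), and Hsp70Bbb was not examined with it. The list did not pass with an estimated correlation (adjusted p = 0.437). A single library as the only source is argued against. For 6 of the 6 called genes both Amyrel heads other than replicate 1 lay above every control head, at 1.67 to 6.54 times the highest control. Of the 20 members 16 had all Amyrel heads above all control heads (for 1 gene chance gives 5%, and 10% for no overlap in either direction). The members are not independent, some being near-identical copies, so the 5% does not apply to the 16 together. The 6 genes were called from these same heads. Another time of day at collection stays open: Clk was higher by 0.42 (adjusted p = 0.0272, 0.0532 with replicate number in the model) and tim stood at -0.97 (adjusted p = 0.118, 0.0198 with replicate number in the model and up to 0.318 over its alternatives). An effect of Amyrel, whose own RNA was higher in these heads, stays open and was not tested.

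Of the 84 genes called higher in all 4 knockdown thoraces against each control separately, 67 rose by more than 1 on the log2 scale in each, Amyrel and the gut gene Npc1b among them. More of the gut that control thoraces hold is argued against as the whole source. It would raise the abundant gut markers alphaTry, betaTry, Jon65Aiii and Jon99Ciii alike. Their sum was 5826 ± 567 CPM in controls (SD, n = 6) and 3861 CPM in knockdowns. In any knockdown library it reached at most 1.24 times the control mean. The argument rests on this sum. The mean of each of the 67 over all knockdown libraries was at least 3.21 times its control mean, but the 67 were chosen for rising. Amyrel RNA may have entered each library with these genes, since within groups its level followed their median over the 12 knockdown libraries (Pearson r 0.91, Spearman rho 0.825, exact permutation p = 0.000772 for each, the smallest possible, r 0.82 without the 2 farthest libraries), as closely as 0.179% of 11195 genes outside the set. Entry at 1 fixed ratio cannot be told apart from a separate response, as the ratio varied between groups by 2.13 (log2) against a median of 0.787, more than for 87.9% of the 66 others, and a response of muscle was not tested.

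Between the control lines 1451 genes were called. Eye and accessory gland RNA in some control thoraces cannot be told apart from line differences: in edgeR's test 0% of the 29 markers were called, 0 also at an unadjusted p under 0.05 and by DESeq2, but each control group holds libraries with and without it, so the markers' median SD within groups was 3.09 (log2) against 0.11 for all genes. Counts made without these libraries cannot decide this. Only replicate 1 of GFP RNAi remained without those high in ninaE, and only replicate 3 of white RNAi without those high in Acp36DE. Line differences in linked stretches of the genome cannot be told apart from other causes, as neighbouring called pairs numbered 206 against 183 with calls shuffled (ratio 1.12, permutation p = 0.029), between the limits set beforehand. No biological explanation was tested.

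All 12 core proteasome genes other than the targets and all 18 regulatory particle genes stood higher in ProsB5 than in ProsB1 RNAi, by a test of the difference itself. Reads that were not aligned, which no comparison uses, made up 3.47% of Ter94 RNAi replicate 1, above the highest control thorax at 1.64%.

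Other splits of the same libraries were refitted with the compared libraries alone as 2 groups, the reference groups pooled as 1. In each of the 5 comparisons with 84 splits, 1 split, the real one, gave as many genes, a share under 0.05. That share takes single libraries as exchangeable, and 84 splits can give no share below 1 of 84. Splits that mix groups put differences between groups into the residual spread, and the median count of the other splits was 0. The share therefore cannot decide whether chance differences between lines gave the counts. The splits do not tell a knockdown from other differences between lines or, for CG6272 RNAi, from a library batch. The real count and the highest other were 1490 and 828 for ProsB1, 2120 and 797 for ProsB5, 5594 and 394 for Ter94, 6081 and 83 for Ter94 against proteasome, and 2084 and 245 for CG6272 RNAi. These splits take Ter94 RNAi replicates 2 and 3 as independent; with the 2 summed as 1 library there were 28 splits, and the real count and the highest other were 4414 and 3 against controls and 5015 and 0 against proteasome RNAi. The highest others set apart the GFP RNAi libraries for ProsB1, ProsB5 and CG6272 RNAi, the white RNAi libraries for Ter94 RNAi, and the ProsB1 RNAi libraries for Ter94 against proteasome RNAi. The 10 splits are too few for a share under 0.05 in white against GFP RNAi (1072 and 0), in ProsB5 against ProsB1 RNAi (327 and 27) and in heads (162 and 1).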

How the results depend on the processing

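Calls against each reference group separately, the data without the 3 controls high in ninaE or the 4 libraries high in Acp36DE, and the summed Ter94 RNAi replicates were chosen after the data were seen. Of 9411 values of named genes under alternatives 8594 kept their side of the threshold, 702 lost and 111 gained a call and 4 reversed. A change of direction was counted only where the gene was called in the main fit or under the alternative. The reversed ones were Cyp6a2 at 0.0713 and y at 0.15 for ProsB1 RNAi against GFP or white RNAi alone, and Cyp6a2 at -0.40 and AttC at -0.18 for CG6272 RNAi against white RNAi alone. Each of the 3 genes also differed between the control lines. RLE scaling shifted the median of all genes by at most -0.0175 and changed the sign of 3 list medians, none of them over 0.011 in size. Both scalings take most genes as unchanged, so their likeness does not test this for Ter94 RNAi, where 58.1% were called. TMM factors were 1.11 to 1.12 for Ter94 RNAi, against 0.986 to 1.01 for ProsB1 and 0.975 to 1.00 for ProsB5 RNAi. Replicate number in the model moved no count by over 1.5 times, and with it 8 named genes lost and 4 gained a call in heads.

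An absolute log2 fold change of at least 1 left 597 genes for ProsB1, 644 for ProsB5, 1263 for Ter94, 187 for white against GFP, 62 for ProsB5 against ProsB1, 1235 for Ter94 against proteasome and 520 for CG6272 RNAi, and 58 in heads, by construction fewer. Against both controls separately 1089, 1735 and 828 remained for ProsB1, ProsB5 and CG6272 RNAi. Without the libraries high in ninaE the counts were 1530, 2274, 536 and 299 for ProsB1, ProsB5, white against GFP and CG6272 RNAi. Without those high in Acp36DE they were 1714, 304, 300 and 341 for ProsB5, white against GFP, ProsB5 against ProsB1 and CG6272 RNAi, with fewer libraries. DESeq2 gave 1023 for ProsB5 against ProsB1 RNAi and 441 for heads. ProsB5 against ProsB1 RNAi gave 327 in a fit of the 2 groups, and CG6272 RNAi 1246 against white RNAi alone and 4328 in a fit of all thorax libraries. The cause of these changes was not tested.

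Leaving out 1 library gave 1505 to 2391 genes for ProsB1, 2502 to 3485 for ProsB5, 5730 to 6718 for Ter94, 828 to 1292 for white against GFP, 371 to 613 for ProsB5 against ProsB1, 5664 to 6414 for Ter94 against proteasome and 1220 to 3147 for CG6272 RNAi, and 25 to 207 in heads. A group left with 2 libraries takes its spread from the whole fit. Without the libraries high in ninaE only replicate 1 of GFP RNAi is left, and without those high in Acp36DE only replicate 3 of white RNAi. Such a group shows no spread of its own, which also bears on the knockdown counts made without these libraries.

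With an estimated correlation the pathway lists called fell from 10 to 0 for ProsB1, 10 to 0 for ProsB5, 7 to 0 for Ter94, 9 to 0 for white against GFP, 9 to 2 for ProsB5 against ProsB1, 7 to 0 for Ter94 against proteasome and 4 to 0 for CG6272 RNAi, and 7 to 0 in heads. Against white RNAi alone ProsB1 RNAi kept 5, and CG6272 RNAi had 7 against GFP and 2 against white RNAi alone. With a different control for each comparison shared calls were 1097 and 951 for ProsB1 with ProsB5, 524 and 570 for ProsB1 with CG6272, 582 and 718 for ProsB5 with CG6272 and 692 and 791 for Ter94 with CG6272 RNAi.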

Other observations

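Apart from the accessory gland and testis marker lists, the genes and tests in this part were chosen after the results were seen.

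Genes outside the fixed lists were lower in all 4 knockdown thoraces than in the controls. The 4 comparisons share the control libraries, so high levels in the controls cannot be told apart from falls in the knockdowns. Whether RNA of other organs carried into thoraces accounts for these genes was not tested. Akh, the adipokinetic hormone gene, stood at 63.5 ± 9.5 CPM in the control thoraces and at 7.01 ± 3.91, 4.73 ± 2.62, 0.332 ± 0.0738 and 6.41 ± 3.42 CPM under ProsB1, ProsB5, Ter94 and CG6272 RNAi (log2 -3.16, -3.74, -7.55 and -3.28), with 62.8 ± 11.8 CPM in control heads. Cyp4g1, a cytochrome P450 gene of the oenocytes that takes part in making cuticular hydrocarbons, stood at 17726 ± 2502 CPM in controls and at 2783 ± 895, 2857 ± 1233, 1849 ± 28.4 and 3979 ± 1328 CPM (log2 -2.67, -2.63, -3.25 and -2.16). The transcription factor gene Hand, expressed in the heart, stood at 8 ± 0.381 CPM in controls and at 4.74 ± 0.888, 5.16 ± 0.391, 2.79 ± 0.425 and 3.12 ± 0.308 CPM (log2 -0.75, -0.63, -1.51 and -1.37). The cuticle protein gene Cpr49Ab fell by 6.83, 7.07, 6.94 and 2.98 on the log2 scale.

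Rises shared by the 4 knockdowns included Npc1b, a sterol uptake gene of the gut, at 1.9 ± 1.8 CPM in controls and 50.9, 55.8, 13 and 19.5 CPM under ProsB1, ProsB5, Ter94 and CG6272 RNAi. In all, 221 genes were higher and 335 lower in the 4 knockdowns, of 10775 tested, and 84 and 152 against each control separately.

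None of 8 accessory gland markers was called over all genes by edgeR in the fit of 15 libraries. In Ter94 RNAi 1 was lower at an unadjusted p under 0.05 and 3 by DESeq2, and against proteasome RNAi 0 passed at an unadjusted p and 1 was higher by DESeq2. In ProsB5 RNAi and in white against GFP RNAi 0 passed either way. In ProsB1 RNAi 6 were lower at an unadjusted p under 0.05 and 8 by DESeq2 (adjusted p = 0.122 for the list). In ProsB5 against ProsB1 RNAi 8 were higher at an unadjusted p, all 8 adjusted over the list alone, and 3 by DESeq2 (adjusted p = 0.152 for the list), which rests on ProsB5 RNAi replicate 1, with Acp36DE at 125 CPM there and at 0.084 and 0.0292 CPM in replicates 2 and 3. In CG6272 RNAi 0 of 7 were called over all genes, with 7 lower adjusted over the list alone, at an unadjusted p and by DESeq2 (adjusted p = 0.146 for the list). Of 9 testis markers 0 were called in the fit of 15 libraries, at an unadjusted p or by DESeq2, and of 6 in CG6272 RNAi 0 were called, with 1 lower at an unadjusted p and 3 by DESeq2.

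In heads, neighbouring genes were called together in 11 pairs against 2.36 with calls shuffled (permutation p = 0.001, the smallest the shuffles give), among them Ir75a with Ir75b and 2 pairs of Hsp70 copies, Hsp70Ba with Hsp70Bbb and Hsp70Bbb with Hsp70Bb, whose reads are hard to place. In thoraces the ratio of such pairs to the shuffled mean was 1.25, 1.12, 1.03 and 1.18 for ProsB1, ProsB5, Ter94 and CG6272 RNAi against controls (permutation p = 0.001 for each). Calls of the head comparison coincided in sign with those of ProsB1, ProsB5, Ter94 and CG6272 RNAi in 34, 45, 33 and 20 genes, against 14.7, 22.4, 42.7 and 15.6 expected of independent lists, and were opposite in 17, 23, 61 and 23.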
